A study of Mus musculus with 8 samples.

How the data were processed

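ATAC-seq libraries from mouse kidney tubuloids came from 4 vehicle-treated and 4 myoglobin-treated samples collected after 12 h. Per the labels' protocols, 50000 cells per sample were lysed and transposed with Tn5 in a single reaction and the fragments were amplified with indexing primers. The series text gives 4 wild-type mice, but no label says which libraries came from the same mouse. The p-values therefore speak for these samples and not for the spread between mice. In the limma fit, the spread at a peak was mostly borrowed from all peaks. The prior variance carried 78.5 degrees of freedom, against 6 from the libraries at that peak.

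Per the submitters' processing notes, the tools named were Trimmomatic 0.39, STAR 2.7.10a, Picard 3.0.0, featureCounts and DESeq2 1.36.0, with the genome build mm10. The role and order of each, the peak caller, the treatment of duplicates and mitochondrial reads, and any shift of reads for the Tn5 insertion site were not given in the sources used here. A shift of a few bases would move few reads across the edges of peaks with a median width of 204 bp. Peaks were given as one set for all libraries, so a region open in few libraries depends on how that set was made.

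The deposited values are whole numbers in one column per library, and are treated as a score, because the deposited columns are scaled values that were rounded to whole numbers. Several facts in the values show this: the totals differ by little between libraries (124415 to 126782), and in each column whole numbers are skipped or over-used at regular steps, as reads multiplied by one factor and rounded would be. The factor of each column was estimated by maximum likelihood over those steps, as 0.749, 0.624, 0.971 and 0.732 for vehicle replicates 1 to 4 and 1.01, 1.53, 1.87 and 1.04 for myoglobin replicates 1 to 4, with a geometric mean of 1.00. The estimate was tested on simulated libraries. Dividing a column by its factor gives estimated reads, from 67609 to 200680 per library.

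The design fixed before the data were examined assumed raw counts and named a limma fit for normalized values. Since the unit is a score, that limma fit was the main test, and quasi-likelihood and Wald tests for counts were not run because the values are not counts. The fit used log2(value + 1), the treatment as the only term, an empirical Bayes variance trend, no filter, and Benjamini-Hochberg adjustment over 6425 peaks with a threshold of 0.05. Fold changes are on the log2(value + 1) scale, which understates the change of low peaks. For the 7 higher peaks with a vehicle mean under 3, ratios of estimated reads were given, taking the most reads that each rounded vehicle value allows. These ratios were corrected for the lower depth of the myoglobin libraries. Their exact binomial 95% counting intervals cover counting error only, because amplified reads are not independent molecules. Gene lists were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry, over the lists with at least 3 peaks. Library measures were compared by exact two-sided permutation over 70 assignments, and locations by two-sided Fisher exact tests.

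Gene names came from the deposited table where it gave one, with 4369 of 4391 symbols found in a RefSeq gene table of GRCm38.p6, the assembly that mm10 names. For peaks without a coding gene in the file, the nearest coding gene by span in that table was named with its distance. The table gives gene spans only, so exons and introns were not used here, and no genome sequence was used.

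The naming rule, fixed before the data were examined, took the 8 largest rises and the 8 largest falls among called peaks with non-overlapping groups and a gene name that is not a predicted or clone name, the 2 members of each list with the smallest p, and 12 genes always reported where measured. The rule gave 8 rises and 1 fall. The other 7 called peaks (at the Lcorl promoter, Pde4b, Specc1l, Phyhipl, upstream of Hmox1, Robo1 and 1600014C10Rik) were named after their values were seen, so that all 16 are given. The 20 lists covered haem, iron and NRF2, glucocorticoid targets, heat shock, tubule injury, NF-kB and inflammation, p53, integrated and endoplasmic reticulum stress, immediate early and AP-1, hypoxia and glycolysis, ferroptosis, proximal tubule, fatty acid oxidation, loop, distal and collecting duct, cell cycle, TGF-beta and matrix, and steroid receptor genes, with endothelial, fibroblast and pericyte, immune and podocyte markers.

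Alternatives were other scalings (median-ratio, total, cyclic loess), pseudocounts of 0.1 and 5, filters at mean values of 1, 10 and 50, each library left out, the replicate number as a block, library weights, a square-root scale, robust variance estimation, a promoter window of 5000 bp, promoters also taken at the ends of coding gene spans (strand not used) or over peaks with an assigned gene only, the analysis without the shallowest libraries (myoglobin replicates 2 and 3) and thinning of the estimated reads to one depth in 20 draws. The fit and the factor estimate were tested on simulated data first, where 0 peaks were called in 50 draws with nothing changed and 2.93% of calls were false with 50 peaks changed per fold size. Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 and statmod 1.5.0.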

Results

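Chromatin accessibility was measured by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into open DNA, in mouse kidney tubuloids. Tubuloids are epithelial structures grown in Matrigel from dissociated tubule cells, here from the renal cortex of wild-type mice. The series compared 4 vehicle-treated libraries with 4 libraries from tubuloids given myoglobin for 12 h. Myoglobin is the haem protein that muscle releases in rhabdomyolysis, and was used here to injure the tubule cells. The series title places the experiment in a study of glucocorticoids and epithelial stress in acute kidney injury, and the only contrast in these libraries was myoglobin against vehicle.

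The deposited table held 6425 peaks on mm10 with a median width of 204 bp. Of these, 4162 (64.8%) lay within 1000 bp of a transcription start site, 615 others had a gene assigned in the table and 1648 had none, so the table mostly described promoters. The median value per peak and library was 16, and the totals ran from 124415 to 126782 because the authors had scaled the libraries to one another. The spacing of the whole numbers in each column gave back the scaling factor and, from it, an estimate of the reads behind each column. Vehicle libraries held an estimated 166153, 200680, 130568 and 171209 reads in peaks (replicates 1 to 4), and myoglobin libraries 123453, 82518, 67609 and 120202. The myoglobin mean was 0.589 times the vehicle mean, and the groups did not overlap (exact two-sided permutation test over 70 assignments, p = 0.0286, the smallest this design allows, and 0.171 after adjustment over 6 library measures). Depth therefore went with treatment, and peak values from myoglobin libraries had the larger counting error.

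**Figure D1:**
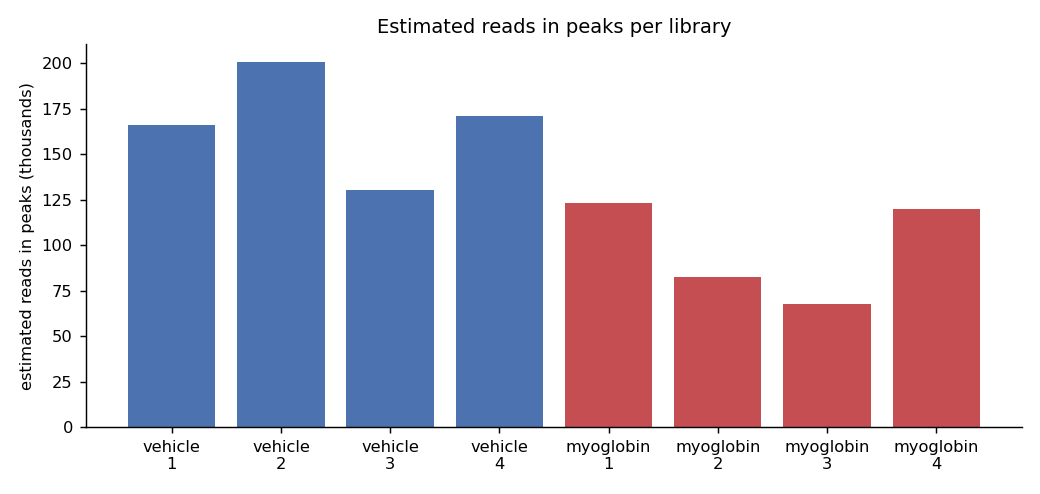
Estimated reads in peaks (vertical axis, in units of 1000 reads) for each of the 8 libraries, 4 vehicle (blue) and 4 myoglobin (red). Every vehicle library lies above every myoglobin library, the closest pair being 130568 and 123453 reads.

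The question of the contrast was which regions opened or closed after 12 h of myoglobin. Peak values rose at 13 of 6425 peaks and fell at 3. Of these 16 peaks, 15 had all 4 myoglobin libraries on one side of all 4 vehicle libraries. For the 7 rises with a vehicle mean under 3, DNA from an outside source was left open. A higher value there need not mean more open chromatin. The largest rises lay inside Hs3st4, which encodes a heparan sulfate 3-O-sulfotransferase, and inside Lcorl, which encodes a nuclear-receptor corepressor-like protein. Others lay in Olfr1423, an olfactory receptor gene, and inside Slc12a3, the thiazide-sensitive sodium-chloride cotransporter of the distal convoluted tubule. A peak upstream of Hmox1, the gene of the haem-degrading enzyme haem oxygenase 1, was also higher. The falls were inside St8sia1, inside Robo1 and near 1600014C10Rik.

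Both Hs3st4 peaks lay far from any other coding gene. At chromosome 7, 124294049 to 124294267, the value went from 1.5 ± 1.0 in vehicle to 79.0 ± 17.8 in myoglobin (SD, n = 4 each), a log2 difference of 5.04 ± 0.30 (SE) with adjusted p = 3.31e-25 by limma. The second Hs3st4 peak, at 124272958 to 124273117, went from 1.5 ± 1.73 to 27.8 ± 7.80, with a log2 difference of 3.73 and adjusted p = 7.60e-11. Because vehicle reads there were so few, folds were also taken from the estimated reads, corrected for the depth of the libraries. This gave a ratio of 45.4 (95% counting interval 23.5 to 100) for the first Hs3st4 peak, from 240 myoglobin and at most 9 vehicle reads. The second had a ratio of 17.6 (8.55 to 42.2), from 83 and at most 8 reads. These intervals cover counting error only.

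Lcorl held 3 of the 13 higher peaks. Its peak at chromosome 5, 45730436 to 45730644, had a value of 1 in every vehicle library and of 30.0 ± 5.89 in myoglobin (log2 difference 3.93, adjusted p = 6.50e-13), with a read ratio of 24.1 (11.3 to 61.4). A neighbouring Lcorl peak, at 45731358 to 45731483, went from 0.50 ± 0.58 to 13.8 ± 3.59 (log2 difference 3.35, adjusted p = 6.98e-06), with a read ratio of 25.5 (8.19 to 128). The promoter peak of Lcorl, 72 bp from its transcription start site at 45857353 to 45858021, was much more open at baseline and rose less, from 47.0 ± 2.71 to 74.0 ± 12.0 (log2 difference 0.63 ± 0.14, adjusted p = 0.0150).

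Within the Slc12a3 span on chromosome 8, 94365575 to 94365822, the value rose from 5.25 ± 3.20 to 25 ± 6.38 (log2 difference 2.14 ± 0.32, adjusted p = 3.29e-06 by limma). Olfr1423 held a peak at chromosome 19, 12036206 to 12036375, that rose from 2.50 ± 1.73 to 18.5 ± 3.70 (log2 difference 2.61, adjusted p = 5.91e-06). Low-valued peaks 26457 bp from Fbxo2 (chromosome 4, 148192828 to 148192926) and 25102 bp from Sub1 (chromosome 15, 11956175 to 11956292) rose by log2 differences of 2.29 and 2.30, with adjusted p = 0.0175 and 0.0459. The Sub1-side rise was uneven, at 11 ± 10.4 in myoglobin against 1.00 ± 0.82 in vehicle.

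The Hmox1-side peak lay outside coding genes, 9637 bp from the Hmox1 span, at chromosome 8, 75083896 to 75084066; the deposited table assigned it to a pseudogene. It rose from 8.25 ± 1.71 to 20.5 ± 5.45 (log2 difference 1.20 ± 0.29, adjusted p = 0.0429). The Hmox1 promoter peak itself, at 75093635 to 75093740, was at 7.5 ± 2.52 in vehicle and 7.5 ± 3.11 in myoglobin (log2 difference -0.03 ± 0.39, adjusted p = 0.993).

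Smaller rises were called inside Pde4b, a cAMP phosphodiesterase gene (chromosome 4, 102494347 to 102494501; log2 difference 1.10, adjusted p = 0.0200), at the promoter of Specc1l, which encodes a cytoskeletal cross-linking protein (chromosome 10, 75211929 to 75212279; 0.91, adjusted p = 0.0175), and 257 bp outside Phyhipl (chromosome 10, 70599397 to 70599699; 0.94, adjusted p = 0.0207). Among the falls, the peak inside St8sia1, the GD3 ganglioside synthase gene, went from 26.5 ± 5.92 to 11.8 ± 3.30 (chromosome 6, 142957043 to 142957380; log2 difference -1.13, adjusted p = 0.0175). The peak 7169 bp from 1600014C10Rik (chromosome 7, 38175986 to 38176110) went from 17.3 ± 4.99 to 4.5 ± 3.32 (log2 difference -2.07, adjusted p = 0.00281); without myoglobin replicate 2, where the value was 0, the difference was -1.37 (adjusted p = 0.033). The peak inside Robo1, an axon-guidance receptor gene (chromosome 16, 72629918 to 72630022), went from 9.75 ± 5.91 to 1.75 ± 2.36 with overlapping groups (log2 difference -2.23, adjusted p = 0.0459). Whether peaks inside gene spans were exonic or intronic was not analysed here.

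**Figure D2:**
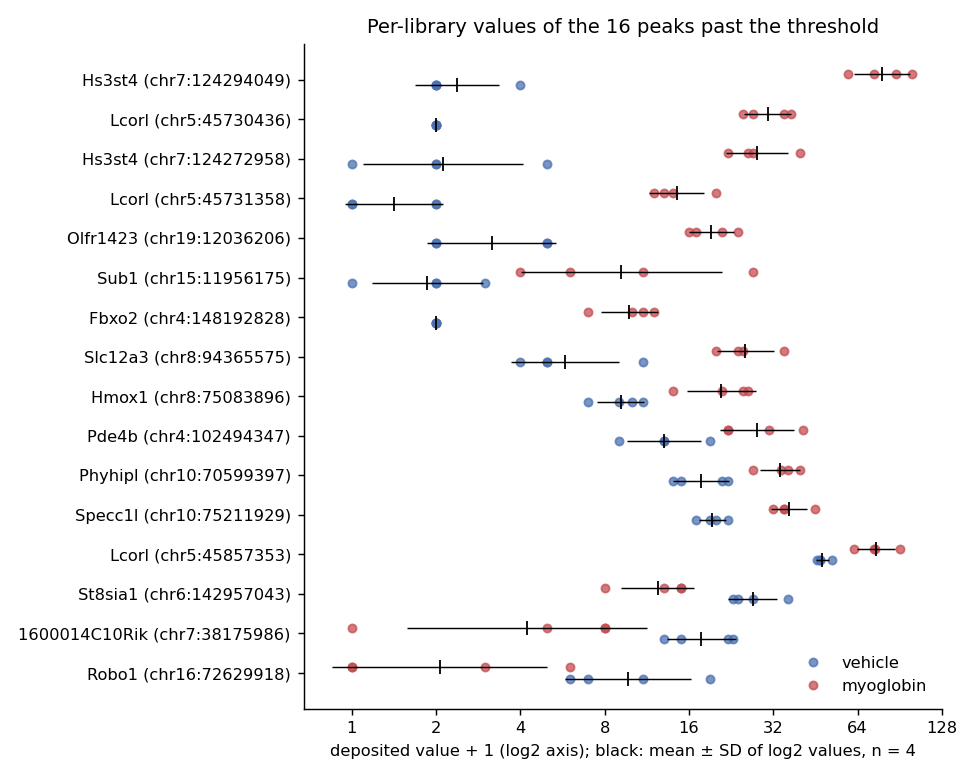
Deposited value plus 1 (horizontal log2 axis) of each library at the 16 called peaks, vehicle in blue and myoglobin in red, with black bars for the mean ± SD of the log2 values (n = 4 per group). The libraries of the groups are apart at 15 of the 16 peaks, and overlap at the Robo1 peak.

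The test was limma on log2 values with Benjamini-Hochberg adjustment, where 488 peaks had an unadjusted p under 0.05 against 321.2 expected by chance. Non-overlapping groups alone were no evidence, as 195 peaks (3.04%) had them and chance gives 2.86%. The 2 peaks inside Hs3st4, the 2 Lcorl peaks away from its promoter, and the Slc12a3 and Olfr1423 peaks kept adjusted p under 0.05 in every alternative that tested them. The other 10 lost the call in some fits with 1 library fewer, with log2 differences there 0.778 to 1.10 times those with all libraries. Of the 16 calls, 7 were left without vehicle replicate 1, 9, 12 and 8 without vehicle replicates 2, 3 and 4, and 13, 13, 10 and 11 without myoglobin replicates 1 to 4; the Hmox1-side call was lost without any of the 4 vehicle libraries and without myoglobin replicates 1, 2 or 4. After thinning all libraries to the depth of the shallowest, 6 peaks were called.

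By the deposited gene assignments, higher peaks lay mostly away from promoters. Of the 13, those of Lcorl and Specc1l (15.4%) were assigned a transcription start site within 1000 bp, against 64.9% of the other 6412 peaks (odds ratio 0.0985, 95% interval 0.0106 to 0.452; two-sided Fisher exact test, p = 0.000366, adjusted over 2 directions 0.000732). The table gave no gene for 9 of the 13, of which the Phyhipl and Slc12a3 peaks lay within 1000 bp of an end of the gene span. Counting every unassigned peak this near to a coding gene end as promoter gave 4 of 13 (30.8%) against 66.3% (Fisher exact p = 0.0143), and among peaks with an assigned gene the share was 2 of 4 against 87.2% (Fisher exact p = 0.0831). Promoter peaks have higher values, and among peaks under the median value, where 8 were higher with myoglobin, the share was 0 against 57.3% (Fisher exact p = 0.00112). All these Fisher tests took peaks as independent. Several higher peaks lay together in Lcorl or Hs3st4, so the p-values may be too small and the interval too narrow. Of the 3 lower peaks, that near 1600014C10Rik counted as promoter, through a small nuclear RNA gene 623 bp away (33.3% against 64.8%, Fisher exact p = 0.285). Without the 2 shallowest libraries, myoglobin replicates 2 and 3, 4 of 12 higher peaks (33.3%) were at promoters (odds ratio 0.271, interval 0.0597 to 1.01, Fisher exact p = 0.0318) and 1 of 7 lower peaks (14.3%, Fisher exact p = 0.0093). Across 1 Mb around the low-valued higher peaks, the other 35 peaks had a median log2 difference of -0.08.

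None of the gene lists fixed for kidney injury moved as a group in the peaks that they had in this table. Of 20 lists, 14 had at least 3 peaks, and camera called 0 of them, with 0 at an unadjusted p under 0.05, a lowest adjusted p of 0.973, and 0.971 with an estimated correlation; fry called 0 as well, with a lowest adjusted p of 0.735. Membership here followed the genes assigned in the deposited table. No such member of any list passed over all 6425 peaks, and only Birc3 passed when adjusted over the list alone. With membership by nearest coding gene within 50 kb, the called peak upstream of Hmox1 belonged to the haem, iron and NRF2 list. By that membership no list passed either (lowest adjusted p 0.985 by camera over 16 lists).

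The stress and injury lists were spread on both sides of 0. Peaks of the haem, iron and NRF2 genes had a median log2 difference of -0.02 over 10 peaks, with Sqstm1, an autophagy adaptor, at -0.41 ± 0.24 (SE) and Prdx1, a peroxiredoxin, at -0.30 ± 0.34. Glucocorticoid targets had a median of -0.11 over 12 peaks, with Arrdc2 at -0.22 ± 0.14, Rhob at -0.40 ± 0.26 and the circadian gene Per1 at -0.19 ± 0.15. Heat shock genes had a median of -0.04 over 13 peaks, with the co-chaperone gene Stip1 at -0.21 and Hsph1 at -0.31 (its second peak at -0.05). Tubule injury genes had a median of -0.07 over 6 peaks, with Prom1 at -0.48 ± 0.26 and Klf6 at -0.25 ± 0.20. The p53 targets had a median of 0.03 over 9 peaks, with Sesn2 at -0.27 (its second peak at 0.12) and Rrm2b at 0.11. Genes of the integrated and endoplasmic reticulum stress responses had a median of -0.08 over 15, with Herpud1 at 0.35 and Sdf2l1 at -0.32.

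In the NF-kB and inflammation list, 0 of 7 peaks passed over all peaks and 1 passed adjusted over the list alone. That was Birc3, which encodes an inhibitor of apoptosis, at chromosome 9, 7872811 to 7873057, where the value was 20 ± 5.35 in vehicle and 31.5 ± 2.65 in myoglobin (log2 difference 0.67 ± 0.21; adjusted p = 0.292 over all peaks and 0.0168 over the list by limma). Nfkb2 stood at 0.53 ± 0.28 (adjusted p = 0.188 over the list), while the median of the list was -0.02. Immediate early and AP-1 genes had a median of 0.03 over 18 peaks, with Ier5 at 0.46 ± 0.26 and Dusp6 at 0.25 ± 0.20.

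Metabolic and cell-state lists did not separate the groups either. Hypoxia and glycolysis genes had a median of 0.01 over 16 peaks, with Ldha at -0.40 ± 0.22 and Pdk1 at -0.38 ± 0.23. Ferroptosis genes had a median of -0.11 over 9 peaks (Aco1 -0.17, Slc3a2 -0.27). Fatty acid oxidation genes had a median of 0.16 over 6 peaks (Acaa2 0.57 ± 0.34 with its second peak at 0.36, Acadm 0.25 ± 0.19). Cell cycle genes had a median of -0.16 over 17 peaks, of which Ccna2, the cyclin A2 gene, was at -0.41 ± 0.19 with an unadjusted limma p of 0.0338 and an adjusted p of 0.610, and Cdk1 at -0.44 ± 0.28. The TGF-beta and matrix list had a median of -0.17 over 4 peaks (Pdgfb -0.29, Skil -0.15), and steroid receptor genes a median of -0.06 over 3 (Nr1d1 0.40, Nr3c2 -0.13). Such single values, none of them called, moved widely when 1 library was left out, as at Nr1d1 (0.06 to 0.65), Klf6 (-0.43 to -0.05) and Cdk1 (-0.64 to -0.18).

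Cell identity could hardly be read from this table. By assigned genes, the proximal tubule list had 2 peaks, at Cryl1 (-0.19 ± 0.25) and at Cdh16 (0.00 ± 0.18). The loop, distal and collecting duct list had 1, at Scnn1g (0.44 ± 0.24), an epithelial sodium channel subunit. The called peak inside Slc12a3 had no assigned gene and was not counted. By nearest coding gene within 50 kb these lists had 7 and 9 peaks, and neither moved as a group (camera adjusted p = 0.985 for each). The endothelial, fibroblast and pericyte, immune and podocyte lists had no peak assigned to their genes. Of the genes chosen in advance for individual report, Hmox1 and Per1 had peaks, while Havcr1, Lcn2, Nr3c1, Fkbp5, Tsc22d3, Lrp2, Hnf4a, Slc34a1, Krt20 and Cdkn1a had none assigned to them in the table.

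**Figure D3:**
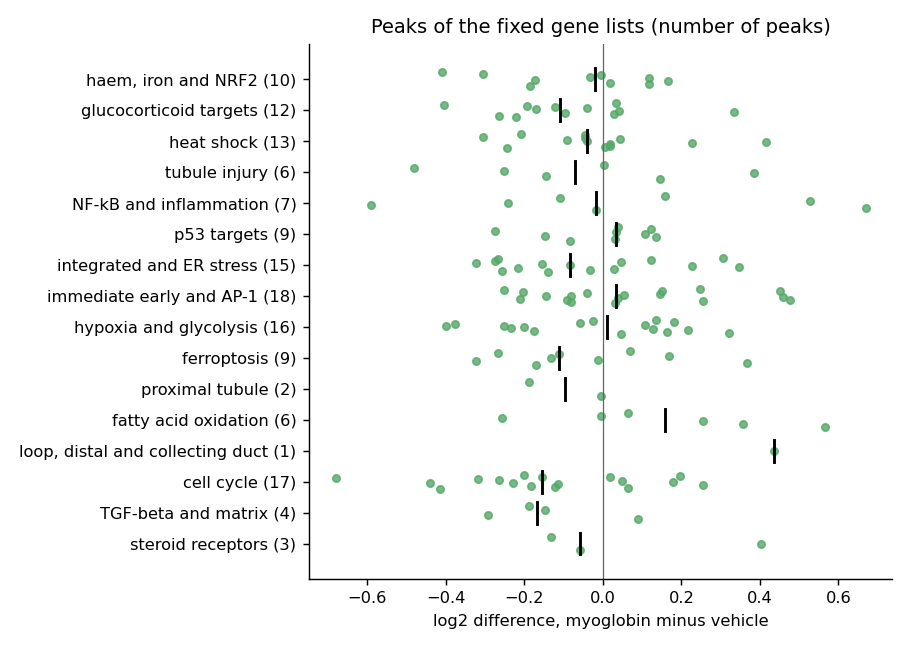
Log2 difference between myoglobin and vehicle (horizontal axis) of each peak in the 16 fixed gene lists that had any, with the number of peaks in parentheses and a black bar at the list median. List medians over at least 3 peaks lie between -0.17 and 0.16.

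Libraries of a group differed by little more than read sampling. The variance between vehicle libraries was 1.15 times, and between myoglobin libraries 1.09 times, what sampling of the estimated reads would give. Beyond sampling, the coefficient of variation was 8.38% in vehicle and 8.47% in myoglobin, while the median part due to sampling was 19.9% and 26.1%. Correlations of log2 values across peaks, which are not independent replicates, were 0.844 to 0.857 among vehicle libraries, 0.742 to 0.810 among myoglobin libraries and 0.757 to 0.828 between groups. The leading principal component (23.1% of variance) set myoglobin replicate 3 apart and the next (18.0%) myoglobin replicate 2, the shallowest libraries. Myoglobin and vehicle libraries did not differ past the threshold in the share of the total in the 100 highest peaks (6.07% against 6.33%, exact permutation p = 0.0857, but 0.0286 without vehicle replicate 1), on chromosome X (0.983% against 1.02%, exact permutation p = 0.229), in promoter peaks (70.7% against 70.5%, exact permutation p = 0.743), in total value (exact permutation p = 0.714) or in the share of peaks above 0 (99.7% against 99.9%, exact permutation p = 0.257).

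In simulated data of this depth and spread, limma recovered 12.6% of peaks changed by a fold of 1.5, 56.0% at a fold of 2, 96.4% at 4 and 99.6% at 8, among 6425 peaks. Each draw changed 50 peaks at each of these folds. The adjustment is stricter where fewer peaks change, so the rates may be too high for these data. They also average over peaks of all heights. Most simulated changes of a fold of 1.5 were thus missed, but the rate at the height of the Birc3 peak was not taken. The Lcorl promoter peak, at a high value, was called at a fold of 1.55.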

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

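In 9 of 110 sets of 4 libraries, 1 library lay far from the other 3 by Dixon's gap test. Chance would give 5.5 such sets for continuous values, but these are small whole numbers. Where 3 libraries have the same value, any other value in the last one is flagged, however near. That was so in vehicle at the larger Hs3st4 peak, Prdx1 and Herpud1, so 9 against 5.5 decides nothing. Among called peaks, these were the Lcorl promoter in vehicle replicate 1 (value 51), the larger Hs3st4 peak in vehicle replicate 3 (value 3, against 1 in the others) and the Slc12a3 peak in vehicle replicate 3 (value 10). Among list members they were Prdx1 in vehicle replicate 3 (7), Birc3 in vehicle replicate 4 (12), Herpud1 in vehicle replicate 2 (18), Scnn1g in vehicle replicate 3 (23), Rhob in myoglobin replicate 4 (10) and Aco1 in myoglobin replicate 3 (43). At the Hs3st4 and Slc12a3 peaks the far vehicle library was the one nearest to the myoglobin group, and both calls stayed without it. No library measure was far from its group.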

How the results depend on the processing

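Library weights, the square-root scale, robust estimation, the filter at 10, nearest-gene list membership, the other definitions of a promoter by assigned genes and gene ends, the omission of the shallowest libraries and thinning were chosen after seeing the data. Of 979 alternative fits of the 49 named peaks, 883 kept direction and side of the threshold, 81 lost the call and 15 turned direction. All 81 losses were at the 16 called peaks, as the other named peaks had no call to lose. The share lost among fits of called peaks was therefore larger than among all 979. The called peaks, 16 in all with 13 higher and 3 lower, numbered 1 (1 and 0) at a mean of at least 50, where 247 peaks were tested, and 9 (8 and 1) with a pseudocount of 0.1. Thinned to one depth, 6 were called (6 and 0; 5 to 8 over 20 draws). Lower peaks numbered 5 with a pseudocount of 5 and with library weights, and 7 without the shallowest libraries. Leaving out each library gave 7 to 15 calls (7 to 13 higher, 0 to 4 lower), with 7, 9 and 8 without vehicle replicates 1, 2 and 4. With the replicate number as a block, 10 peaks were called (1 lower), and 9 with the block and cyclic loess (8 higher, 1 lower). Labels share only a number: deviations of same-numbered libraries correlated at 0.026, 0.015, -0.013 and 0.0085, and 0 of the 4 numbers matched best with their own. The cause of these shifts was not tested, apart from fewer peaks, libraries or reads where the setting removes them.

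The named peaks that turned direction had not passed the threshold. Pdk1 stood at 0.255 and Aco1 at 0.0078 without the shallowest libraries. Cdh16 stood at 0.0018 with median-ratio scaling, 0.048 with library weights, 0.0952 without the shallowest libraries, 0.0039 thinned, and -0.173 to 0.1 with each library left out. The Hmox1 promoter stood at 0.00663 with cyclic loess, alone or with the block, and at -0.225 to 0.196 with each library left out. The promoter share of higher peaks was 100% (1 peak) at a mean of at least 50, 33.3% (4 of 12) without the shallowest libraries, 25% (2 of 8) with a pseudocount of 0.1, 22.2% (2 of 9) with the block, 50% (2 of 4, no longer past the threshold) over peaks with an assigned gene and 0 to 18.2% with each library left out, and that of lower peaks 100% (1 peak) with the block, alone or with loess, and over peaks with an assigned gene, 25 to 100% with each library left out, and 14.3% (1 of 7, Fisher exact p = 0.0093) without the shallowest libraries. The difference in estimated reads was -80900 to -57530 with each library left out, where p reached 0.0571 in 35 assignments, and -68710 paired by number, with exact sign-flip p = 0.125, the smallest possible. The share in the 100 highest peaks differed by -0.3484 to -0.1491 points, passing without vehicle replicate 1 (exact permutation p = 0.0286). The total value differed by -82.92 to 706.1 and the promoter share by -0.2025 to 0.4208 points.

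Folds of low peaks moved with the pseudocount: at 0.1 and 5 the log2 difference was 5.77 and 3.68 for the larger Hs3st4 peak and -3.92 and -1.11 for Robo1.

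No list passed in any of 21 alternatives (lowest adjusted p 0.723). Count-based tests and voom weights were not run because the values are not counts, the filters at 1 and none removed no peak, and no list kept 3 peaks at a mean of 50.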

Other observations

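The tests of an outside DNA source, of random placement and of calls kept at one depth were chosen after the result was seen. Just short of the threshold, 6 peaks had adjusted p between 0.05 and 0.1. They included a promoter peak of Smarca4, the gene of a chromatin-remodelling ATPase (chromosome 9, 21615971 to 21616163; 9.75 ± 2.87 in vehicle, 21 ± 2.16 in myoglobin, log2 difference 1.07, adjusted p = 0.0701 by limma), and peaks inside Hivep3 (1.06, adjusted p = 0.0547) and Micall2 (0.70, adjusted p = 0.0701). A low-valued peak 176593 bp from Matn1 stood at 1.89. On the lower side were a promoter peak of Znf143 (Zfp143 in the RefSeq table), a zinc-finger transcription factor gene (-1.25, adjusted p = 0.0753), and a peak at chromosome 7, 38201027 to 38201191, 3541 bp from 1600014C10Rik (-1.20, adjusted p = 0.0979), on the same side as the called fall near that gene.

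Chance and depth were weighed for the 16 called peaks. Of the 35 splits of the 8 libraries into 4 and 4, only 1, the real one, gave as many calls. The highest of the others gave 3. This argues against chance assignment of libraries but does not exclude it, as 1 of 35 is the smallest share possible. The real split also parts the libraries by depth, so its rank cannot tell treatment from depth. With all libraries thinned to one depth, 6 of the 16 peaks, those of Hs3st4, Slc12a3, Olfr1423 and 2 of Lcorl, were still called. Their adjusted p by limma was up to 0.0167, each in at least 16 of 20 draws. These calls therefore did not need unequal read numbers. Thinning makes only read numbers equal, so it cannot speak to any other difference between the groups that went with depth. For the other 10 (adjusted p by limma from 0.212 when thinned) the difference in read numbers stays open too. The median ratio of thinned to full log2 difference, 1.03, decides nothing, since random thinning leaves an expected fold about as it was.

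Of the higher peaks, 7 were nearly empty in vehicle and higher in every myoglobin library (2 each in Hs3st4 and Lcorl, with those at Olfr1423 and near Fbxo2 and Sub1), though the Sub1-side peak had only 2 estimated reads in myoglobin replicate 2. A shared gain of the surrounding 1 Mb is argued against by the other 35 peaks there, with a median log2 difference of -0.0762 (interquartile range 0.389) against a median rise of 3.35. That median pools the neighbours of all 7 peaks, so it cannot speak for a single site or for a shorter gained segment. DNA from an outside source of fixed composition in the myoglobin preparation could fill empty sites alike, and stays open. The proportions of the 7 peaks varied somewhat between the 4 myoglobin libraries (chi-square with tables drawn by permutation, p = 0.0252). That lay between the bounds set for a fixed ratio (0.05 or more) and for a changing one (under 0.01). The test covers counting error only, so spread between samples or from amplification could give it too. The Sub1-side peak was the most uneven, at 5, 2, 14 and 10 estimated reads in myoglobin replicates 1 to 4. A test without it was not run, so the p-value does not show that the ratios of the other peaks varied. The called peaks formed 4 pairs within 200 kb, all in Hs3st4 or Lcorl, but that window was set after the pairs were seen, so the comparison with 10000 random draws (permutation p = 1e-04, the smallest they can give) decides nothing about placement. Newly opened elements inside Hs3st4 and Lcorl are a hypothesis that these data leave beside the outside source, and sequence at the sites was not analysed here.

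For the peak upstream of Hmox1, the hypothesis of a rise shared across haem, iron and NRF2 genes was tested on the 15 other peaks nearest to genes of that list. Their median log2 difference was 0.0172 (95% bootstrap interval -0.185 to 0.119), below the 0.5 chosen in advance as the bound for such a rise. This argues against a rise of that size across most of these peaks. A median cannot speak for a rise at only a few of them. The Hmox1 promoter peak was among them, and promoter and distal sites were pooled. The median therefore cannot speak for distal sites alone. The Hmox1 promoter peak stood at 7.5 in both groups (log2 difference -0.03), and the upstream call was kept in 10 of 21 alternatives (adjusted p from 0.00377 to 0.443). Whether the upstream site responds to myoglobin on its own was not tested.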
